A study of Mus musculus with 6 samples.

How the data were processed

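MicroRNA (miRNA) levels were measured in whole dorsal skin of C3H/HeJ mice, an inbred strain in which some animals spontaneously develop alopecia areata (AA), an autoimmune loss of hair. Per the labels' protocols, total and small RNA was purified with a column kit, tailed with poly(A), joined to a tag for Cy3 staining and hybridised by a service provider to µParaflo chips, which are microfluidic chips carrying miRNA detection probes. The extract protocol also names biotin-labelled cRNA, and which step applied to these arrays is not known. The 6 arrays were 1-colour arrays and each held 1 sample. Groups were taken from the sample descriptions: 3 arrays of AA skin with hair loss and 3 of normal haired skin from unaffected mice. The design note speaks of several samples taken from each mouse without tying samples to arrays, so it is not known which arrays, if any, share a mouse, and p-values measure only the spread between these arrays, which may in part be technical.

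The scanner files deposited by the authors hold a raw intensity per spot (the mean over its pixels), neither background-subtracted nor normalized, with no local background column. Each array had 3968 spots, of which 3535 were miRNA spots (707 mouse miRNA probes, 5 spots each, in an older miRBase naming), and 145 were empty or background control spots. The image software, its settings, the miRBase release and a genome build are not given in the sources used here, so no genomic coordinates are printed. The value table deposited by the authors holds 755 probes as processed intensity on a linear scale. Set against the scanner values over the probes detected on all 6 arrays, its log2 values correlated at r = 0.956 to 0.999 per array, and the median ratio to the background-subtracted signal ran from 0.400 to 3.72. Its column medians were 43.2, 38.0 and 39.0 in unaffected replicates 1 to 3 and 37.8, 44.3 and 34.2 in AA replicates 1 to 3. Per these comparisons the values are linear, background-subtracted and scaled between arrays, with no centring of miRNAs. The method behind the scaling is not given in the sources used here, and the table served as an alternative.

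From the raw intensities, the background was corrected with normexp (offset 50) on all spots in limma 3.58.1 (R 4.3.3). The log2 values of the 5 spots of a probe were averaged, and the arrays were quantile-normalized over the 707 miRNA probes. A probe was called detected on an array where its mean raw intensity exceeded the 95th percentile of the empty control spots of that array. The 157 miRNAs detected on at least 3 of the 6 arrays were tested. AA was compared with unaffected skin by limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The offset compresses differences of dim probes.

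Before the data were examined, 17 miRNA lists (cell types of skin, inflammation, hair growth and miRNA families) were fixed, and the 9 lists with at least 3 tested members were compared with the remaining miRNAs by camera (preset correlation 0.01, Benjamini-Hochberg over the 9 lists). Camera with an estimated correlation and fry were run beside it. Also fixed beforehand was the rule for naming miRNAs. It took the largest changes past the threshold and, where fewer than 10 passed in a direction, filled to 10 per direction by the smallest unadjusted p. The list members and the 5 miRNAs of highest mean intensity were added. The mean of each list was also tested by an exact permutation test (two-sided), whose smallest possible p with 3 arrays against 3 is 0.1.

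The labels do not say that the replicate numbers pair mice, so the main design has no block. The alternatives, also fixed beforehand, changed the background correction, the normalization between arrays, the detection filter, the source of values, the variance model, the spot summary and the replicate block, and left out each array in turn. Removing each array's trend on target GC content was added after seeing the data. A run without AA replicate 3 and unaffected replicate 1 together was also made after seeing the data and is not reported, because the second of these had been picked partly on its miRNA values. A slide block was not run, because the files used here name no slide.

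The procedure was tested on simulated data built from the means and spreads of the 157 miRNAs, in 20 runs with 30 changed miRNAs each. It recovered 27.5% of 2-fold, 77.0% of 4-fold and 96.0% of 8-fold changes, with 4.52% false calls. The adjustment is stricter where fewer miRNAs change, so recovery may be lower in data with fewer than 30 changed miRNAs. The number of arrays limits the precision. Nearly identical family members can cross-hybridise, and such probes are not independent measurements.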

Results

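The miRNA content of whole dorsal skin was profiled on 6 arrays, 3 from C3H/HeJ mice with spontaneous AA (skin with hair loss) and 3 from unaffected mice (normal haired skin). The 1 comparison that the design implies asks which miRNAs differ between diseased and unaffected skin. Values are normalized log2 intensities, given as mean ± SD over the 3 arrays of a group, and differences are AA minus unaffected with the standard error (SE) of the limma fit.

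The 5 probes of highest mean intensity, named by a rule fixed beforehand, were those of miR-205, an abundant miRNA of epidermal keratinocytes, miR-709, let-7c, miR-23a and miR-23b. Intensities of different probes do not rank the abundance of miRNAs. miR-205 stood at 12.89 ± 1.11 in AA and 13.23 ± 0.20 in unaffected skin (SD, n = 3 each). let-7c stood at 13.22 ± 0.49 and 12.71 ± 0.66, and miR-709 at 13.17 ± 0.44 and 12.79 ± 0.11. miR-23a stood at 12.46 ± 0.68 and 13.03 ± 0.45, and miR-23b at 12.56 ± 0.71 and 12.92 ± 0.24. None of these differences exceeded the spread between arrays in the limma fit (adjusted p = 0.727 to 0.867).

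Arrays differed in signal and in detection. Of 707 miRNA probes, 97, 202 and 202 were detected in unaffected replicates 1 to 3 and 147, 115 and 157 in AA replicates 1 to 3. The median raw intensity of empty spots was 274, 168 and 189 in unaffected replicates 1 to 3, against 209, 490 and 530 in AA replicates 1 to 3. The median miRNA spot was dimmer than the median empty spot in unaffected replicate 1 (168), in AA replicate 2 (399) and, by a small margin, in unaffected replicate 2 (166). Detection, set by the empty spots of each array, was therefore strict on unaffected replicate 1 and AA replicate 2, the arrays with the fewest detected probes. For the 88 probes detected on all 6 arrays, the median raw intensity was 16.9 and 11.4 times the empty-spot level in unaffected replicates 2 and 3. The same ratio was 4.20 in unaffected replicate 1, 3.33 and 3.24 in AA replicates 1 and 2, and 1.46 in AA replicate 3. Over the 157 tested miRNAs, normalized values correlated between arrays at r = 0.73 to 0.91 within the unaffected group, 0.83 to 0.92 within AA and 0.80 to 0.90 between groups. The ranges within and between groups overlapped. Unaffected replicate 1 correlated better with AA replicates 1 and 2 (0.90 and 0.85) than with unaffected replicates 2 and 3 (0.73 and 0.84). Its correlation with AA replicate 3 was 0.80.

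**Figure D1:**
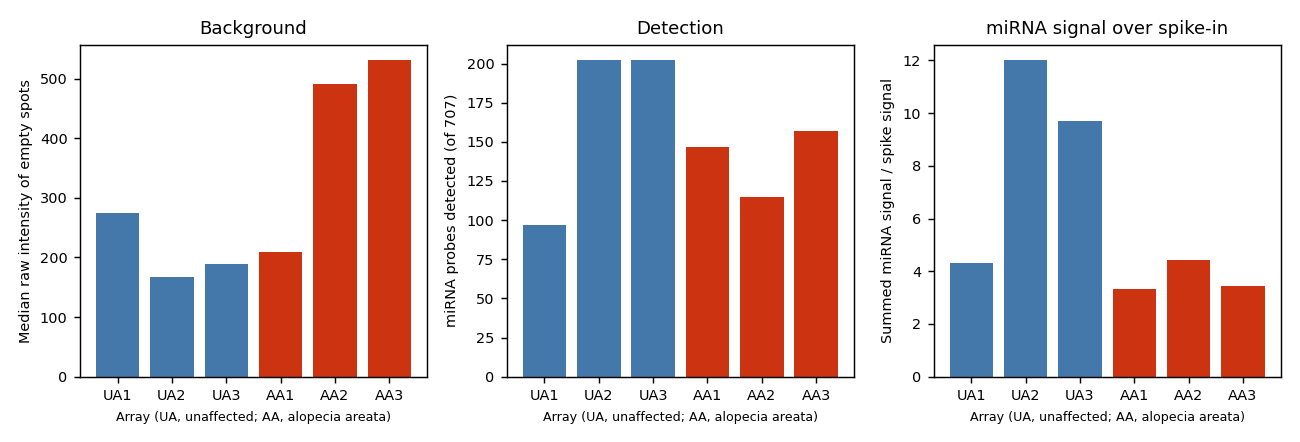
Bars give, for each of the 6 arrays (blue, unaffected, UA; red, AA), the median raw intensity of empty spots, the number of detected miRNA probes out of 707, and the summed background-subtracted signal of the 157 tested miRNAs divided by that of the spike-in probe PUC2PM-20B. Empty spots are brightest in AA replicates 2 and 3 (490 and 530), and the miRNA signal over the spike-in is 9.72 or more in unaffected replicates 2 and 3 and lies between 3.33 and 4.44 on the other 4 arrays.

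No single miRNA differed between AA and unaffected skin after adjustment: 0 were higher and 0 lower at an adjusted p under 0.05 (limma, 157 miRNAs, smallest adjusted p = 0.402). At an unadjusted p under 0.05, 4 were higher and 8 lower in AA, where chance alone gives 7.85 in all. The values of the groups did not overlap for 18 miRNAs (7 higher, 11 lower), or 11.5% of those tested, where chance gives 10%. The 4 higher and 8 lower became 30 and 2 with arrays scaled to the 75th percentile of the probes detected on all arrays, and 0 and 62 with the 75th percentile of all probes, with 0 adjusted calls in limma under either. Without unaffected replicate 1, 2 miRNAs passed as higher (miR-1937a at a log2 difference of 2.81 and miR-1937b at 3.01) and 3 as lower (miR-1 at -3.31, miR-26b at -1.75 and miR-30b at -1.69). Without unaffected replicate 2, miR-2861 (2.97) and miR-705 (2.00) passed as higher; miR-705 was chosen for mention after its values were seen. The same omissions moved others the opposite way: miR-1937b was 1.05 and miR-1937a 0.91 without unaffected replicate 2, and miR-2861 was 0.97 without unaffected replicate 1. The target sequences of miR-1937a and miR-1937b differ by 1 edit, so these probes may share signal and are not independent calls.

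The list of miR-29 and miR-30 miRNAs, tested through 5 miR-30 members and miR-29a alone of the miR-29 family, was lower in AA skin. All 6 tested members had lower means in AA, with a mean log2 difference of -0.95, and the list differed from the other miRNAs by camera with its preset correlation (adjusted p = 0.000248). The call was lost with an estimated correlation (adjusted p = 0.319, correlation between members 0.68). Fry, which tests whether the members move one way on balance and does not compare them with other miRNAs, gave an adjusted p of 0.263. Over the 19 alternative settings the preset-correlation adjusted p ran from 3.73e-07 to 0.0176. The list means of the AA arrays were 9.55, 9.47 and 9.13, all below those of the unaffected arrays at 9.78, 10.63 and 10.59, which is the smallest p that the exact permutation test allows (p = 0.1). The inflammation list reached the same permutation p, with higher means in AA. Adjusted over the list alone, 3 of the 6 members passed, miR-30b, miR-30c and miR-30e, and over all miRNAs tested 0 did.

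The miR-30 probes with the smallest p were those of miR-30c and miR-30b. miR-30c (UGUAAACAUCCUACACUCUCAGC) measured 9.44 ± 0.28 in AA and 10.83 ± 0.39 in unaffected skin, a 2.61-fold lower level (log2 difference -1.39, SE 0.39, limma adjusted p = 0.402). miR-30b (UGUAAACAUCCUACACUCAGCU) measured 9.39 ± 0.49 and 10.85 ± 0.40, 2.75-fold lower. miR-30e was 2.23-fold and miR-30a 1.90-fold lower in the AA means, and the 3 AA arrays lay below the 3 unaffected arrays for each of miR-30a, miR-30b, miR-30c and miR-30e. miR-30e was detected on 2 of 3 arrays in each group, and its log2 difference was -0.32 with arrays scaled to the 75th percentile of the probes detected on all arrays. That scaling moved the median of all tested miRNAs to 0.53. miR-30d (log2 difference -0.38, SE 0.36) and miR-29a (-0.40, SE 0.54) had smaller differences. The target sequences of miR-30b and miR-30c differ by 3 edits, and that of miR-30a differs by 1 from both miR-30d and miR-30e, so these probes may share signal. Signal over the empty spots was lower on every AA array (1.46 to 3.33 times) than on every unaffected array (4.20 to 16.9 times). The members have target GC contents of 40.9% to 50%. The slope of log2 intensity on target GC content was higher on every AA array (0.0068 to 0.17 per 10 percentage points) than on every unaffected array (-0.36 to -0.077). The skeletal muscle list, whose mean was 10.76 ± 0.63 in AA and 11.69 ± 1.14 in unaffected skin, also had lower means in AA and did not pass.

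**Figure D2:**
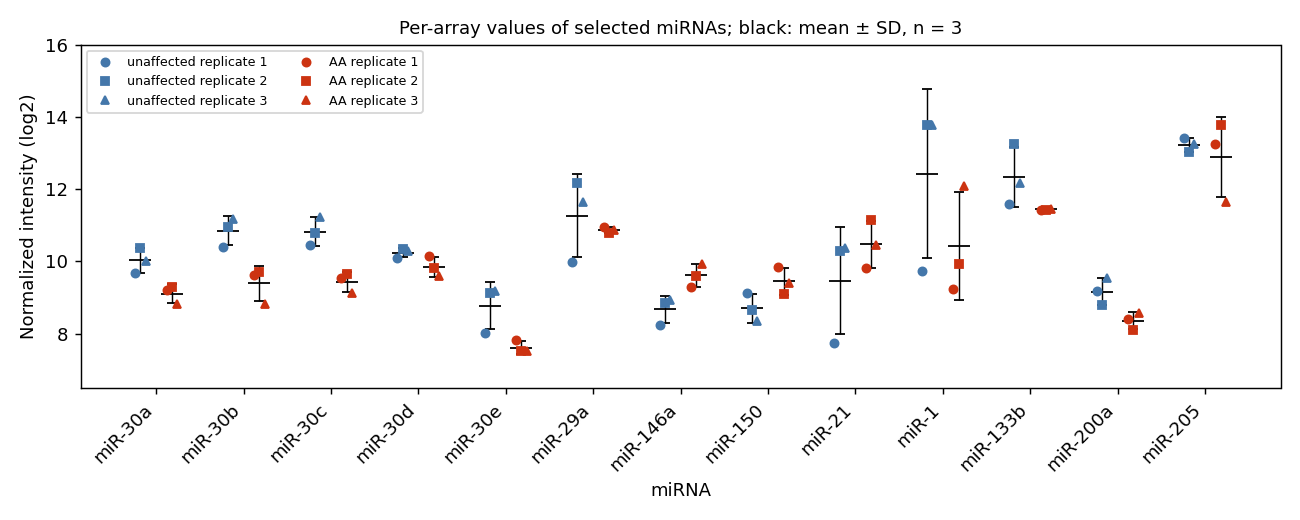
Points give the normalized log2 intensity of each array for 13 miRNAs (blue, unaffected; red, AA; the symbol marks the replicate), with black bars for the group mean ± SD (n = 3). The AA points of miR-30a, miR-30b, miR-30c, miR-30e, miR-133b and miR-200a lie below all unaffected points. Those of miR-146a lie above them, and miR-1 ranges from 9.25 to 13.78 over the 6 arrays.

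Other miRNAs with the smallest p among those of lower mean in AA did not pass the adjusted threshold (limma adjusted p = 0.566 to 0.588). miR-10b, which is encoded within a Hox gene cluster, measured 8.11 ± 0.25 in AA and 9.30 ± 0.52 in unaffected skin, 2.29-fold lower. miR-26b measured 8.15 ± 0.80 and 9.51 ± 0.75. miR-100 measured 8.01 ± 0.48 and 9.01 ± 0.45. The star strand let-7d* measured 7.18 ± 0.36 and 8.36 ± 0.90, and was detected on 1 of 3 AA arrays. Without unaffected replicate 1 its log2 difference was -0.65 in place of -1.18. miR-15a measured 7.55 ± 0.31 and 8.51 ± 0.72 and was also detected on 1 of 3 AA arrays. miR-466i measured 8.38 ± 0.50 and 9.24 ± 0.25. With arrays scaled to the 75th percentile of the probes detected on all arrays, the log2 differences were -0.69 for miR-10b, -0.33 for miR-100, -0.052 for miR-15a and 0.050 for let-7d*. That setting moved the median of all tested miRNAs to 0.53, and relative to it each of these stayed lower in AA.

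The lymphocyte and inflammation lists had higher means in AA but did not pass. The lymphocyte list had 4 tested members, all with higher means in AA (mean log2 difference 0.49). Its adjusted p by camera was 0.0953, and 0.319 with an estimated correlation. It passed without AA replicate 3 (mean difference 0.73, adjusted p = 0.0407, and 0.482 with an estimated correlation) and with each array's GC trend removed (0.61, adjusted p = 0.0227, and 0.232 with an estimated correlation), over a range of 0.0227 to 0.329 in the 18 alternatives that tested it. miR-146a, a feedback inhibitor of inflammatory signalling, measured 9.61 ± 0.32 in AA and 8.68 ± 0.37 in unaffected skin, and all AA arrays lay above all unaffected arrays (log2 difference 0.94, SE 0.39, limma adjusted p = 0.566). miR-150, abundant in mature lymphocytes, measured 9.45 ± 0.38 and 8.71 ± 0.40. miR-181a and miR-181b differed by 0.17 (SE 0.56) and 0.11 (SE 0.47). The inflammation list also had 4 tested members with higher means in AA (mean difference 0.59, camera adjusted p = 0.0953, and 0.319 with an estimated correlation). With the GC trend removed it passed (0.84, adjusted p = 0.0108, and 0.232 with an estimated correlation), over a range of 0.0108 to 0.536 in the same 18. Without AA replicate 2 its mean difference was 0.31. Its list means of 9.11, 10.02 and 9.29 in AA replicates 1 to 3 all lay above the 8.91, 8.68 and 9.07 of unaffected replicates 1 to 3 (exact permutation p = 0.1). It shares miR-146a with the lymphocyte list. Its other members are miR-21 (10.48 ± 0.66 in AA, 9.47 ± 1.48 unaffected), miR-146b (difference 0.26, SE 0.44) and miR-31 (0.15, SE 0.79). The lower unaffected mean of miR-21 rested on replicate 1, at 7.76 against 10.28 and 10.37 in replicates 2 and 3. miR-21 and miR-146a were each detected on 3 of 3 AA arrays and 2 of 3 unaffected arrays. The lists' higher means turned negative, at -0.49 for both, when arrays were scaled to the 75th percentile of all probes, a setting that moved the median of all tested miRNAs to -0.95. miR-142 and miR-155 probes did not reach the detection minimum. The neutrophil miRNA miR-223, the 1 tested member of the myeloid list, measured 7.60 ± 0.71 in AA and 8.13 ± 0.43 in unaffected skin. It was detected on 1 of 3 AA arrays and 2 of 3 unaffected arrays.

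Further miRNAs of higher mean in AA likewise did not pass (limma adjusted p = 0.566 to 0.624). miR-296-5p measured 8.22 ± 0.42 in AA and 7.30 ± 0.10 in unaffected skin. miR-222, which targets the cell-cycle inhibitor Cdkn1b, measured 9.35 ± 0.29 and 8.64 ± 0.23, and miR-210, a hypoxia-induced miRNA, 7.94 ± 0.50 and 7.25 ± 0.10. The dim miR-210 was detected on 2 of 3 AA arrays and 1 of 3 unaffected arrays, and miR-296-5p on 3 and 2. The log2 differences of miR-296-5p and miR-210 were 0.92 and 0.69 in the main setting and 0.49 and 0.35 with the GC trend removed. They were 2.01 and 1.89 with arrays scaled to the 75th percentile of the probes detected on all arrays. That scaling moved the median of all tested miRNAs to 0.53. miR-2134 measured 10.11 ± 0.073 and 9.31 ± 0.47. The largest differences in means were those of miR-1937b (13.23 ± 0.32 against 11.30 ± 2.06), miR-1937a (13.45 ± 0.38 against 11.65 ± 2.00) and miR-2861 (12.48 ± 0.83 against 10.72 ± 2.16), whose unaffected arrays spread widely. miR-720 measured 12.50 ± 0.88 and 11.42 ± 0.91. With single arrays left out, its log2 difference of 1.09 ran from 0.69 without AA replicate 3 to 1.59 without unaffected replicate 1. Removal of the GC trend gave 0.66 for miR-720, 1.34 for miR-1937b, 1.32 for miR-1937a, 0.53 for miR-2861 and 0.47 for miR-2134. The main setting gave 1.93, 1.80, 1.76 and 0.80 for miR-1937b, miR-1937a, miR-2861 and miR-2134. miR-222 went from 0.71 to 0.69. With arrays scaled to the 75th percentile of all probes, and without normalization, the AA means of miR-146a, miR-150, miR-222, miR-720 and miR-2134 were the lower ones, but above the median shift of the tested miRNAs.

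Skeletal muscle miRNAs, which in whole dorsal skin can come from the muscle layer beneath it, had lower means in AA. All 4 tested members were lower on average (mean difference -0.93), and the list did not pass (camera adjusted p = 0.0953, and 0.651 with an estimated correlation). miR-1 stood at 9.25, 9.94 and 12.09 in AA replicates 1 to 3 and at 9.74, 13.78 and 13.78 in unaffected replicates 1 to 3. Without unaffected replicate 1 the list passed with a difference of -1.51 (camera adjusted p = 0.00189, and 0.394 with an estimated correlation), and without AA replicate 3 with -1.26 (adjusted p = 0.0317, and 0.493 with an estimated correlation). Without unaffected replicate 2 the difference was -0.48 and the list did not pass (adjusted p = 0.323). It also passed with arrays scaled to the 75th percentile of the probes detected on all arrays (-0.89, adjusted p = 0.455 with an estimated correlation) and without normalization between arrays (-2.27, adjusted p = 0.556 with an estimated correlation). Its adjusted p ran from 0.00189 to 0.495 over all alternatives. miR-133b measured 11.44 ± 0.022 in AA and 12.34 ± 0.84 in unaffected skin, with no overlap between groups. miR-133a measured 11.72 ± 0.26 and 12.47 ± 0.87, and miR-206 9.46 ± 1.03 and 9.50 ± 0.78.

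Keratinocyte miRNAs did not pass: 6 of 7 tested members had lower means in AA (mean difference -0.34, camera adjusted p = 0.214). The mean difference was -0.14 without unaffected replicate 3, -0.070 with the GC trend removed and -0.0076 with arrays scaled to the 75th percentile of the probes detected on all arrays. That scaling moved the median of all tested miRNAs to 0.53, so relative to it the list stayed lower in AA (camera adjusted p = 0.182). Among them miR-200a measured 8.36 ± 0.24 in AA and 9.16 ± 0.37 in unaffected skin with no overlap between groups, and miR-200b 9.23 ± 0.45 and 9.86 ± 0.48. The epidermal differentiation miRNA miR-203 differed by -0.048 (SE 0.46). The hair follicle growth list (7 tested members, mean difference 0.019 but median -0.048, camera adjusted p = 0.826) and the fibroblast and smooth muscle list (6 members, -0.14, 0.826) did not pass. Examples are miR-214 (difference 0.48, SE 0.44), miR-24 (0.33, SE 0.37), miR-152 (-0.80, SE 0.40) and miR-145 (-0.27, SE 0.37). The clusters of miR-17 and miR-92a (8 members, -0.11, camera adjusted p = 0.826) and the let-7 family (9 members, -0.074, 0.936) did not pass either. The members of smallest p were miR-106a (-0.79, SE 0.42), miR-19b (-0.66, SE 0.48), let-7f (-0.67, SE 0.51) and let-7g (-0.60, SE 0.46). They do not stand for their lists: the clusters had 4 members of higher and 4 of lower mean in AA, and the let-7 family 3 and 6. miR-106a and miR-19b were each detected on 1 of 3 AA arrays and 2 of 3 unaffected arrays. The direction of these last 4 lists changed with the array scaling, the GC correction or single arrays left out.

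Lists with fewer than 3 tested members were not tested as groups. The red-cell miRNA miR-451 stood at 11.79, 8.07 and 13.18 in AA replicates 1 to 3 and at 11.47 to 11.85 in unaffected skin, and miR-486 at 9.74, 8.26 and 11.85 in AA and at 11.54, 9.70 and 9.40 in unaffected replicates 1 to 3. The endothelial miR-126-3p measured 9.19 ± 0.45 in AA and 10.20 ± 1.12 in unaffected skin, where replicates 1 to 3 stood at 9.02, 11.24 and 10.35. Of the adipocyte list, miR-378 measured 9.68 ± 0.47 and 9.12 ± 0.73, and miR-193b 7.65 ± 0.38 and 8.17 ± 0.57. The neuronal list had miR-128 (difference -0.75, SE 0.42), the imprinted Dlk1-Dio3 cluster miR-127 (-0.15, SE 0.36), and the miR-183 cluster miR-183 (-0.48, SE 0.39) and miR-182 (-0.026, SE 0.48). Of the 2 melanocyte probes, 0 reached the detection minimum.

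**Figure D3:**
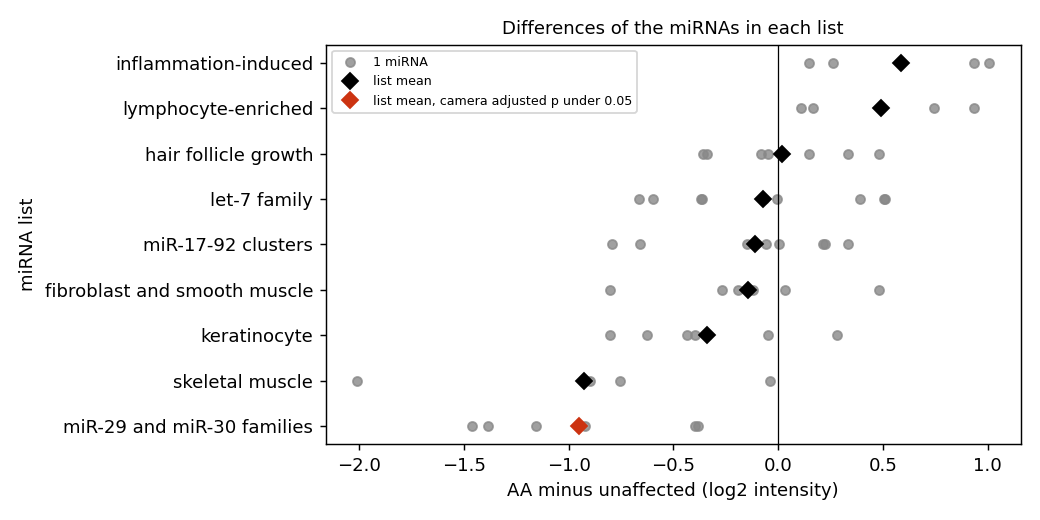
Each grey point is the AA minus unaffected difference of 1 miRNA (log2 intensity, horizontal axis) in the 9 tested lists (vertical axis), and diamonds are list means, red where camera with its preset correlation gave an adjusted p under 0.05. The 6 members of the miR-29 and miR-30 list all lie below 0, with a mean of -0.95.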

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

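Of the 19 alternatives, removing the GC trend was chosen after seeing the data and the others were fixed before. The miR-29 and miR-30 list kept its direction and its preset-correlation call in all 19, with mean differences from -2.31 to -0.71, and had no call with an estimated correlation in any. Fry, a test of one-way movement that does not compare the list with other miRNAs, passed only without unaffected replicate 1 (adjusted p = 0.0434). The counts of single miRNAs stayed at 0 higher and 0 lower except when single arrays were left out, which gave 0 to 2 higher and 0 to 3 lower. The calls came without unaffected replicate 1 (2 higher, 3 lower) and without unaffected replicate 2 (2 higher). With the replicate block there were 0 higher and 0 lower, with 3 and 7 at an unadjusted p under 0.05; same-numbered arrays deviated from their group means with correlations of 0.14, -0.10 and -0.12, and not every array correlated best with its own number. The block changed no call. Scaling to the 75th percentile of the probes detected on all arrays moved the median of the tested miRNAs to 0.53 and gave 30 higher and 2 lower at an unadjusted p under 0.05, scaling to that of all probes moved it to -0.95 with 0 higher and 62 lower, and no normalization to -0.84 with 0 and 38, against 4 and 8 in the main setting. Without a detection filter these counts were 17 and 32, and with probes detected on all arrays (88) they were 1 and 4.

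The number of lists called was 1 in the main setting, 2 with the 75th percentile of detected probes and without normalization, 3 with the GC trend removed, and 1 to 3 with single arrays left out. The skeletal muscle list passed at -0.89 under that percentile and at -2.27 without normalization (adjusted p = 0.455 and 0.556 with an estimated correlation), and ran from -1.51 to -0.48 with single arrays left out. The GC correction called the lymphocyte (0.61) and inflammation (0.84) lists, both lost with an estimated correlation (adjusted p = 0.232). Single omissions gave the lymphocyte list 0.35 to 0.73, with a call only without AA replicate 3 (adjusted p = 0.482 with an estimated correlation), the inflammation list 0.31 (without AA replicate 2) to 0.80 and the keratinocyte list -0.46 to -0.14. Under the 75th percentile of all probes and without normalization, in that order, signs turned for the lymphocyte list (-0.49, -0.39), the inflammation list (-0.49, -0.39), the hair follicle list (-1.49, -1.39), miR-146a (-0.34, -0.24), miR-2134 (-0.59, -0.49), miR-222 (-0.50, -0.40), miR-720 (-0.48, -0.38) and miR-150 (-0.46, -0.36). Relative to the moved median, the lymphocyte and inflammation lists and these 5 miRNAs kept their direction. The 75th percentile of detected probes turned the signs of let-7d* (0.050), the hair follicle list (-0.020), the fibroblast list (0.046) and the miR-17 and miR-92a clusters (0.38). All of these values lay below the moved median of 0.53. Relative to it, let-7d*, the fibroblast list and these clusters kept their lower direction, while the hair follicle list turned. Signs also turned for the hair follicle list under cyclic loess (-0.037, with a median of -0.043), the miR-17 and miR-92a clusters with probes detected on all arrays (0.14) and after the GC correction (0.030), and the let-7 list after the GC correction (0.31). Single omissions gave -0.11 to 0.16 for the hair follicle list, -0.31 to 0.070 for the fibroblast list, -0.32 to 0.11 for the miR-17 and miR-92a clusters and -0.33 to 0.14 for the let-7 list. The causes were not tested. Signal over background, lowest in AA replicate 3, limits dim miRNAs, and the simulation, with 30 changed miRNAs, recovered 27.5% of 2-fold changes. The slide block was not run, since the files name no slide.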

Other observations

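Chosen after the results were seen were the set of 5 miR-30 probes, the miR-30 tests without AA replicate 3 and with muscle as covariate, both tests on the signal of AA replicate 3, the count over other splits, the GC correction and the grouping of probes by their CCA end. Beyond the fixed lists, 5 tested probes have targets that end in CCA, the bases found at the 3' end of mature tRNAs: miR-720, miR-1937a, miR-1937b, miR-1937c and miR-223. miR-1937b (AUCCCGGACGAGCCCCCA) stood at 12.90, 13.25 and 13.54 in AA replicates 1 to 3, and at 13.54, 9.49 and 10.87 in unaffected replicates 1 to 3. miR-1937c stood at 8.16, 9.27 and 9.17 in AA and at 10.91, 7.24 and 7.55 in unaffected replicates 1 to 3. The GC-rich target of miR-2861 (GGGGCCUGGCGGCGGGCGG) stood at 11.85, 12.17 and 13.42 in AA and at 9.15, 13.18 and 9.83 in unaffected skin.

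Across the 157 tested miRNAs, the difference between AA and unaffected skin was more positive at higher GC content of the target (Pearson r = 0.55, Spearman rho = 0.49, permutation p = 0.0001 for each, the smallest that 10000 resamples can give; miRNAs are not independent replicates). The 10 named miRNAs of higher mean in AA had a mean GC content of 64.3%, the 10 of lower mean 42.5% and all tested miRNAs 51.9%.

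Lower miR-30 values in AA are a hypothesis for follow-up, with a mean difference over 5 probes of -1.06 (SE 0.26), where the fixed list with miR-29a gave -0.95. The family was singled out after the values were seen, so this SE does not test whether the pattern holds. After each array's linear GC trend was removed, -0.84 (SE 0.23), and -0.71 for the fixed list, remained. A linear GC trend was thus not the whole source of the difference on these arrays, and other effects of base composition stay open. Without AA replicate 3, -0.96 (SE 0.28), and -0.86 for the fixed list, remained, so the difference did not rest on that array alone. AA replicates 1 and 2 (9.27 and 9.20) already lay below every unaffected array (9.74 to 10.38), so this outcome could be foreseen. A different share of muscle stays open. With the muscle list as covariate, fitted with a common slope for both groups, -0.94 (SE 0.32) remained. With so few arrays that SE is itself uncertain. The lowest unaffected miR-30 mean (9.74) went with the lowest unaffected muscle mean (10.41). The lowest AA miR-30 mean (8.78) went with the highest AA muscle mean (11.47). With 3 arrays per group, whether a common slope describes both groups cannot be judged, so the covariate fit decides nothing about muscle. Signal over empty spots stays open, since it was lower on every AA array (1.46 to 3.33) than on every unaffected array, and unaffected replicate 1, the weakest of its group (4.20 against 11.4 and 16.9), also had the lowest unaffected miR-30 mean (9.74 against 10.32 and 10.38); disease, hair-cycle stage and other cell types stay open and untested.

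The CCA-ending probes had a higher mean in AA by 0.92 (SE 0.81), which is within the spread between arrays (exact permutation p = 0.4, 3 against 3 arrays, smallest possible 0.1). Without normalization between arrays the difference was -0.067 (SE 0.59), which decides nothing about scaling between arrays: the median of all tested miRNAs moved from -0.039 to -0.84 in that setting, and relative to it the difference was 0.96 before and 0.78 after. After the GC correction it was 0.60 (SE 0.79), so a GC trend cannot be told apart from the pattern, because the remainder is smaller than its error. The members did not move alike, with miR-223 at 7.60 in AA and 8.13 in unaffected skin, and whether any of these targets come from tRNA was not tested.

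The array of AA replicate 3 had the weakest signal over background. Its spike-in probe PUC2PM-20B read 23814, below the 36160 to 47756 of the other 5 arrays, yet above their median divided by 2, so poor hybridisation or scanning stays open as a partial cause. Its miRNA signal over the spike-in was 3.43, above the 3.33 of AA replicate 1 and below the other arrays. That ratio cannot decide whether the sample held less miRNA, because PUC2PM-20B was itself weakest on this array. The spike-ins a2-PUC2PM-20B and a3-PUC2PM-20B read 39744 or more on every array. Before division by a spike-in, the summed signal of the tested miRNAs was the lowest on AA replicate 3 (79896, next 119722 on AA replicate 1). No biological explanation was tested, since the pattern concerns 1 array.

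For the count of 0 passing miRNAs, a comparison with other splits decides nothing, because any split gives a count of 0 or more. The 6 arrays allow 10 splits into 3 and 3, which are also too few for a share under 0.05. The real split gave 0, and the highest other split gave 1, with 12 and 16 miRNAs at an unadjusted p under 0.05. That other split set AA replicates 1 and 2 with unaffected replicate 1 against the remaining arrays.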
